A study of Mus musculus with 18 samples.

How the data were processed

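Ribosome profiling and RNA-seq were done on livers of male mice of 5 to 8 weeks, per the labels, from hepatocyte-conditional Secisbp2 or Trsp knockouts and matched wild type littermates. For profiling, about 100 mg of tissue was digested with RNase I and monosomes were collected through 50% sucrose, per the labels' protocols. For RNA-seq, polyA RNA was enriched and fragmented. Footprints and fragments of 20 to 40 nt were made into small RNA libraries and sequenced for 50 cycles. The labels state 3 mice per genetic background, while the deposited tables hold 2 libraries per assay for Secisbp2 wild type, Secisbp2 knockout and Trsp knockout and 3 for Trsp wild type.

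The authors deposited RPKM values in 3 tables, per the file headers: footprints 5' of the UGA codon, footprints 3' of it, and RNA-seq reads. Reads were aligned with Bowtie 0.12.8 to mm9, per the submitters' processing notes. How the mapped reads behind the RPKM were counted, which filters and annotation were used, how windows were set and how reads shared by similar genes were counted is not given in the sources used here. Each table holds 23 selenoprotein genes. Current symbols came from a reference gene table of assembly GRCm38.p6, used for names alone: 11 genes had the same symbol and 12 were matched by a synonym. No coordinates are given because the authors' build differs from that table's. A single cell, Selenof 3' of the UGA in Secisbp2 wild type replicate 1, held a date in place of a number. Its serial number, 263.871 RPKM, corresponds to a whole 521 reads, while a day earlier or later gives 519.026 or 522.974 reads, and it was used as the value.

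In the deposited tables a gene's RPKM values are whole multiples of the worth of a single read, and all 311 footprint values above 0 and all 203 RNA values above 0 were within 0.02 of a whole number of reads, which the recovery itself required of each gene. This gave the read numbers quoted and the libraries' depth relative to each other, from 1 to 4.08 for footprints and from 1 to 5.60 for RNA-seq, where Secisbp2 wild type replicate 1 was the shallowest. The recovery was tested on simulated data, where 34 of 35 footprint genes and windows and 23 of 23 RNA genes came back exactly. The absolute number of mapped reads is unknown. Reads without molecular identifiers are not independent molecules, so that exact intervals and floors of 3 reads cover counting error only.

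Values were tested as log2(RPKM + 0.5), for genes with a mean of at least 1 RPKM in the tables used, with limma 3.58.1 in R 4.3.3. Fold changes on this scale understate the change of low genes. All 4 groups entered a single fit and shared an estimate of the spread, since each group has 2 or 3 livers. P-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. UGA redefinition was the log2 ratio of the 3' to the 5' density of the same footprint library. Translational efficiency was tested as the interaction of assay and genotype in a fit over footprints 5' of the UGA and RNA-seq. The comparisons were each knockout against its own wild type, the difference of the knockout effects, and wild type against wild type. Groups of 2 against 2 or 2 against 3 libraries allow no useful exact permutation test of a single gene, so the limma test pools the spread over genes. The test was checked on 100 simulated tables per comparison with known changes. At 2-fold and 4-fold it found 92.9% and 100% for mRNA, 64.4% and 88.1% for footprints 5' of the UGA, 51.5% and 94.6% for those 3' of it, 28.7% and 59% for redefinition and 60% and 88.7% for translational efficiency in the Secisbp2 comparison. The Trsp comparison gave 95% and 99.8%, 64.6% and 90.1%, 61.2% and 93.3%, 32.1% and 66.4%, and 58.8% and 89.3%. Unchanged genes made up 6.81% of the calls for redefinition in the Secisbp2 comparison and 1.8% to 3.7% in the others. Python 3.11.15 with numpy 2.4.6, pandas and matplotlib was used for reading and figures.

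The design, the threshold, the gene lists, the alternatives fixed in advance and the rule for named genes were fixed before the data were examined. That rule took each gene past the threshold, at most 30 per comparison, and Gpx1, Gpx3, Gpx4, Selenop, Selenow, Selenoh, Txnrd1, Txnrd2, Selenof, Selenok, Selenos, Selenot, Msrb1, Sephs2 and Dio1 whatever their p. Other genes named without a call were chosen after their values were seen. The lists were all selenoproteins, glutathione peroxidases, thioredoxin reductases, deiodinases, endoplasmic reticulum, CXXU redox motif, mRNAs that follow the selenium supply, housekeeping selenoproteins, and genes with a UGA close to the stop codon. Further lists were the selenocysteine machinery, NRF2 targets and markers of other liver cells. These last 3 had 0 members in the tables and were not analysed here. Of the deiodinases Dio2 and Dio3 were under the RPKM minimum, as was Selenon, and Selenov is not in the tables. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and all selenoproteins with fry, a limma rotation test, whose p was adjusted over the comparisons. Camera compares a list with the other genes of the table, here all selenoproteins, while fry tests whether the genes move on balance one way. No list passed camera's threshold with an estimated correlation. Relations across genes were given as Pearson's r and Spearman's rho with two-sided tests of 100000 permutations.

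Alternatives fixed in advance were a pseudocount of 0.1 or 1, no filter on low values, a fit with the groups of the contrast alone, the replicate number as a block, both wild type groups pooled or exchanged as control, and leaving out each library in turn. Where that left a group with a single library, that library was assumed to vary like the other groups. A planned scaling to genes other than selenoproteins was not run because the tables hold none. Alternatives chosen after seeing the data were precision weights from the read numbers, a minimum mean of 10 reads, the date cell left out, a block by liver for translational efficiency, and scaling every library to the same median ratio or median level of the selenoproteins.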

Results

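Selenoprotein mRNAs and the ribosomes on them were measured in livers of wild type mice and of mice that had lost, in hepatocytes, either Secisbp2 or Trsp. Secisbp2 encodes a protein that binds the SECIS element, a hairpin in selenoprotein mRNAs, and Trsp encodes the transfer RNA that carries selenocysteine to UGA codons. There were 9 footprint libraries and 9 RNA-seq libraries. For each assay they comprised 2 Secisbp2 wild type, 2 Secisbp2 knockout, 3 Trsp wild type and 2 Trsp knockout livers. The values covered 23 selenoprotein genes and no other gene, so they did not show how the rest of the transcriptome moved. Secisbp2 and Trsp themselves were not among the genes, so the loss of the targeted genes was not analysed here. Over the selenoproteins, the footprint libraries held 2970 to 13705 reads 5' of the UGA codon and 699 to 16856 reads 3' of it, and the RNA-seq libraries held 48753 to 221637 reads. The labels' library codes put the Secisbp2 wild type livers, the Secisbp2 knockout livers and all Trsp livers into 3 separate sets, so that Secisbp2 genotype and library set cannot be told apart.

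The first question was how far selenoprotein mRNA levels depend on Secisbp2. In Secisbp2 knockout livers, Gpx1 mRNA, which encodes the glutathione peroxidase that clears hydrogen peroxide in the cytosol, was 326 ± 58.1 RPKM (SD, n = 2) against 2020 ± 13.9 RPKM (SD, n = 2) in wild type. Its log2 change was -2.64 (SE 0.135, limma adjusted p = 3.82e-07). Selenop mRNA, for the selenium transport protein that the liver secretes, was 326 ± 57.6 RPKM against 1744 ± 247 RPKM (SD, n = 2 each), a log2 change of -2.42 (SE 0.164, adjusted p = 1.78e-06). Dio1, the deiodinase that activates thyroid hormone, fell by 2.54 on the log2 scale (SE 0.252, adjusted p = 2.26e-05), and Gpx4, the peroxidase that protects membrane lipids, by 1.44 (SE 0.167, adjusted p = 6.28e-05). For each of these 4 mRNAs, both knockout libraries lay below both wild type libraries.

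Across the 20 mRNAs tested in Secisbp2 knockout livers, 10 fell, 4 rose and 6 did not pass, with a median log2 change of -0.39. The other mRNAs that fell were Sephs2 (-1.75), which makes selenophosphate, Selenow (-1.73), Selenoh (-1.17), Selenos (-0.95), Selenof (-0.73) and Msrb1 (-0.48). The 4 that rose did so by small amounts. They were Selenoi (0.51), an ethanolamine phosphotransferase, Txnrd1 (0.50), the cytosolic thioredoxin reductase, Selenoo (0.50) and Selenot (0.31). Of these, Selenot came to -0.11 with the wild type groups pooled (adjusted p = 0.702) and to -0.39 with the other colony's wild type (adjusted p = 0.00735). Selenoi lost its call with the groups pooled and came to -0.01 with the other colony's wild type (adjusted p = 0.927). Gpx3 (-0.30), Selenok (-0.24), Txnrd2 (-0.18), Gpx2 (-0.16), Txnrd3 (0.15) and Selenom (0.27) did not pass. All 10 falls held when any single library was left out, but that of Gpx4 was lost with the wild type groups pooled (-0.85, adjusted p = 0.0646) and shrank to -0.46 with the other colony's wild type (adjusted p = 0.0185). The rises were less stable: Txnrd1 (adjusted p = 0.0592) and Selenoi (adjusted p = 0.0856) lost their calls without Secisbp2 knockout replicate 1. Selenot lost its call without any of 6 libraries, among them Secisbp2 wild type replicate 2 (adjusted p = 0.160). Without Secisbp2 wild type replicate 1, Gpx3 (-0.56, adjusted p = 0.0113), Selenok (-0.44, adjusted p = 0.0194) and Txnrd3 (0.38, adjusted p = 0.0290) passed as well, and without replicate 2 Gpx2 (-0.75, adjusted p = 0.0467) and Selenom (0.72, adjusted p = 0.0253) did.

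By the gene lists, all 4 mRNAs known to follow the selenium supply (Gpx1, Selenow, Selenoh and Msrb1) fell in Secisbp2 knockout livers, and all 4 passed adjusted over the list alone. The limma test camera, which compares a list with the other selenoproteins, gave this list an adjusted p = 0.252. Of the 4 glutathione peroxidases, 2 fell (Gpx1 and Gpx4), and 2 passed adjusted over the list alone (camera adjusted p = 0.458). Among the 3 thioredoxin reductases 1 rose (Txnrd1) and none fell, which was also the count adjusted over the list alone (camera adjusted p = 0.276). The 6 tested selenoproteins of the endoplasmic reticulum were split, with 2 higher (Selenoi, Selenot), 2 lower (Selenos, Selenof), a median of 0.02 and a mean of -0.14; 4 passed adjusted over the list alone (camera adjusted p = 0.303). Of the 4 housekeeping selenoproteins, 2 rose (Selenoi, Txnrd1) and 1 fell (Gpx4), with a median of 0.16, a mean of -0.15 and 3 calls adjusted over the list alone (camera adjusted p = 0.303). Of 4 selenoproteins with a CXXU redox motif, 1 rose (Selenot) and 2 fell (Selenow, Selenoh), and 3 passed adjusted over the list alone (camera adjusted p = 0.863). Among the 6 genes whose UGA lies close to the stop codon, 2 rose (Txnrd1, Selenoo) and 1 fell (Selenos), with 3 calls adjusted over the list alone (camera adjusted p = 0.252). Dio1 was the tested deiodinase. Taken as a single set, the 20 selenoprotein mRNAs moved down on balance (adjusted p = 8.22e-05 by fry, a limma rotation test of direction).

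**Figure D1:**
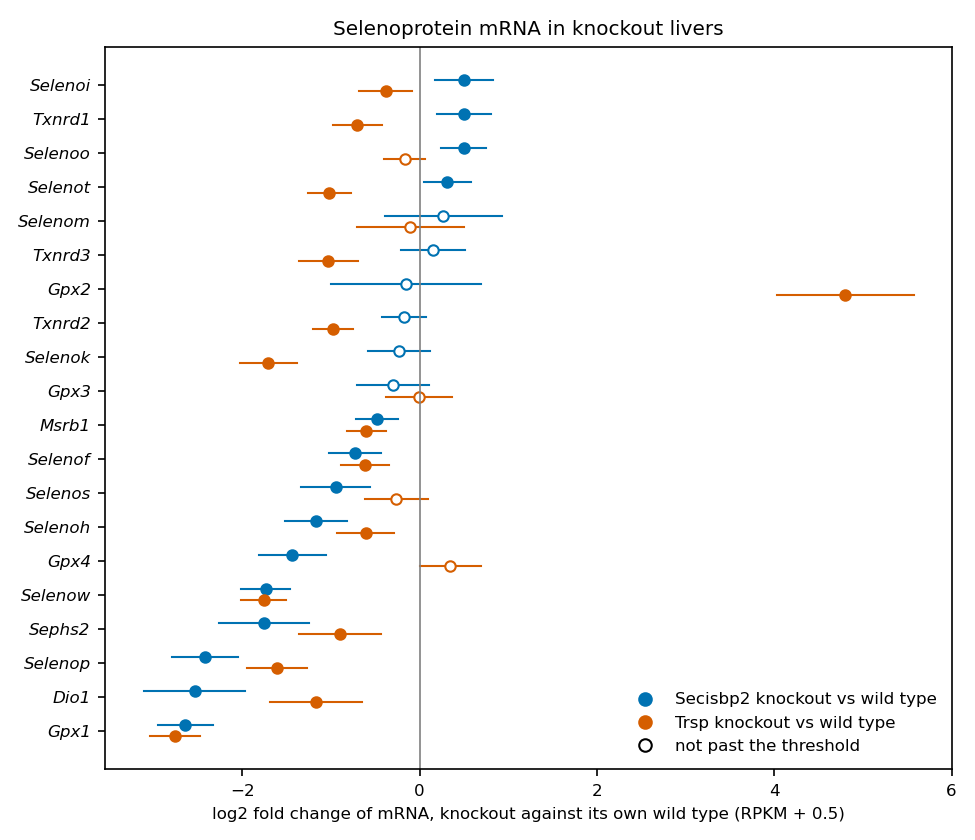
Log2 fold change of mRNA, as knockout against its own wild type with 0.5 added to each RPKM, for 20 selenoproteins. Points give the limma estimate, lines its 95% confidence interval, blue the Secisbp2 knockout (2 against 2 livers), orange the Trsp knockout (2 against 3 livers) and open points genes that did not pass; Gpx1 was the lowest point of both knockouts, at -2.64 and -2.76, and Gpx2 in the Trsp knockout the highest at 4.80.

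The direction of these changes rests on the authors' scaling, since no other genes were available to check it. With every library scaled to the same median log2 ratio of the selenoproteins, a choice made after seeing the data that sets their median change near 0 by construction, the Secisbp2 knockout mRNA changes shifted up by 0.50. The split became 6 higher and 8 lower (5 and 9 at the same median level, which shifted them by 0.26), Msrb1 turned from lower to 0.02, and of the 4 mRNAs that follow the selenium supply 3 were lower. Under the same scaling the median of the list with a UGA close to the stop codon turned from -0.01 to 0.46.

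For the Trsp knockout, the question was what the loss of the selenocysteine transfer RNA itself did to the same mRNAs. Gpx1 mRNA was 307 ± 12.5 RPKM (SD, n = 2) against 2079 ± 105 RPKM (SD, n = 3) in wild type, a log2 change of -2.76 (SE 0.124, limma adjusted p = 1.23e-07). Selenow, a small thioredoxin-like selenoprotein, fell by 1.76 on the log2 scale (SE 0.111, adjusted p = 1.11e-06). Selenok, a membrane protein of the endoplasmic reticulum, changed by -1.71 (SE 0.141, adjusted p = 5.21e-06), and Selenop by -1.61 (SE 0.150, adjusted p = 1.09e-05). Gpx4 mRNA was 346 ± 11.1 RPKM (SD, n = 2) against 275 ± 48.8 RPKM (SD, n = 3) and did not pass (log2 change 0.35, adjusted p = 0.0631). Without Trsp wild type replicate 3 it did, at 0.48 (adjusted p = 0.00783). With the other colony's wild type as control Gpx4 mRNA was lower, at -0.64 (adjusted p = 0.00813).

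The mRNA that rose in Trsp knockout livers was Gpx2, a glutathione peroxidase best known from the gut lining. It had 783 reads in the 2 knockout libraries and 3 reads in the 3 wild type libraries, at 11.2 and 18.9 RPKM against 0 to 0.0817 RPKM. The ratio of the read rates was 331 (exact 95% interval 113 to 1607, counting error only), but the wild type groups differed in Gpx2. It was at 2.34 ± 1.56 RPKM (SD, n = 2) in Secisbp2 wild type livers, and against these as control the log2 change in the Trsp knockout was 2.53 for mRNA (adjusted p = 0.000274) and 1.93 for footprints 5' of the UGA (adjusted p = 0.00239). Against its own wild type the limma log2 change was 4.80 (SE 0.340, adjusted p = 1.91e-06) and, with 0.5 RPKM added to each value, understated the ratio. Gpx2 footprints 5' of the UGA rose too, with 48 reads against 0 in its own wild type, which is at least 21.0-fold higher against a floor of 3 reads over the wild type group.

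In Trsp knockout livers, 14 of the 20 mRNAs fell, 1 rose and 5 did not pass, with a median log2 change of -0.66. Besides those named, Dio1 (-1.17), Txnrd3 (-1.03), Selenot (-1.02), Txnrd2 (-0.98), Sephs2 (-0.90), Txnrd1 (-0.70), Selenof (-0.62), Selenoh (-0.61), Msrb1 (-0.60) and Selenoi (-0.38) fell. Selenos (-0.26), Selenoo (-0.17), Selenom (-0.11) and Gpx3 (adjusted p = 0.976) did not pass. Leaving out any single library kept 14 of the 15 calls; Selenoi lost its call without Trsp knockout replicate 1 (adjusted p = 0.0644), Trsp knockout replicate 2 (adjusted p = 0.138), Trsp wild type replicate 1 (adjusted p = 0.0761) or Trsp wild type replicate 2 (adjusted p = 0.0811). Selenos passed without either Secisbp2 wild type replicate (adjusted p = 0.0294). Several of these falls hung on the control: Dio1 came to -0.78 with the wild type groups pooled (adjusted p = 0.121) and -0.20 with the other colony's wild type (adjusted p = 0.519). Sephs2 came to -0.40 (adjusted p = 0.522) and 0.34 (adjusted p = 0.226), Selenof to -0.28 (adjusted p = 0.522) and 0.23 (adjusted p = 0.179), and Selenoi to -0.17 (adjusted p = 0.543) and 0.14 (adjusted p = 0.486).

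All 3 thioredoxin reductases fell in Trsp knockout livers, 3 adjusted over the list alone (camera adjusted p = 0.796). The 4 mRNAs that follow the selenium supply fell again, 4 adjusted over the list alone (camera adjusted p = 0.448). Of the 6 genes with a UGA close to the stop codon 4 fell (Selenok, Txnrd1, Txnrd2 and Txnrd3), and of the 6 of the endoplasmic reticulum 4 fell (Selenok, Selenot, Selenof and Selenoi), each with 4 calls adjusted over the list alone (camera adjusted p = 0.804 and 0.830). Of the 4 with a CXXU motif 3 fell (Selenow, Selenot, Selenoh), and of the 4 housekeeping genes 3 fell (Txnrd1, Txnrd2, Selenoi), each with 3 calls adjusted over the list alone (camera adjusted p = 0.804 for both). The glutathione peroxidases were split between Gpx2 up and Gpx1 down, with 2 calls adjusted over the list alone (camera adjusted p = 0.0676). The whole set moved down on balance (fry adjusted p = 5.43e-05). With libraries scaled to the selenoproteins' median ratio, these mRNA changes shifted up by 0.56, leaving 4 higher and 7 lower, with 2 of 3 thioredoxin reductases and 2 of 4 mRNAs that follow the selenium supply lower. Under that scaling Selenoi turned to 0.16 and Selenoo to 0.39 (adjusted p = 0.0184), and the median of the endoplasmic reticulum list turned from -0.50 to 0.05 and that of the housekeeping list from -0.54 to 0.00434. With every library at the same median level the changes shifted up by 1.17 and the balance turned, to 11 higher and 3 lower.

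Footprints 5' of the UGA, which come from ribosomes that have started translation, largely followed the mRNAs in Secisbp2 knockout livers. Gpx1 fell by 3.46 on the log2 scale (SE 0.632, limma adjusted p = 0.00281), Dio1 by 3.41 (SE 0.282, adjusted p = 6.15e-05) and Selenop by 2.63 (SE 0.274, adjusted p = 0.000164). Of the 20 genes tested, 9 fell, none rose (11 had an unadjusted limma p under 0.05 in either direction) and 11 did not pass. The others that fell were Sephs2 (-2.16), Selenow (-1.44), Selenof (-1.42), Gpx4 (-1.12), Selenot (-1.06) and Selenos (-1.01). Msrb1 (0.02), Txnrd1 (0.22), Txnrd2 (0.00307), Selenok (1.27), Gpx3 (1.04) and Selenoh (-1.64) did not pass. With the replicate number as a block Selenok, Gpx3 and Selenoh passed, as did Gpx2 (-0.90, adjusted p = 0.0419). Selenow rested on 3 and 7 reads in the knockouts and 6 and 9 in wild type, and lost its call with precision weights from the read numbers (-1.27, adjusted p = 0.0672). With the groups of the comparison alone in the fit the calls for Gpx4, Selenos (adjusted p = 0.0654 each) and Selenow (adjusted p = 0.0667) were lost. Gpx4 also lost its call with the wild type groups pooled (-0.72, adjusted p = 0.118) and with the other colony's wild type (-0.45, adjusted p = 0.183), as did Selenot (-0.51 and -0.14, adjusted p = 0.430 and 0.824). Of the 9 falls, 6 held without any single library; without Secisbp2 knockout replicate 2 the calls for Selenos (adjusted p = 0.0695) and Selenot (adjusted p = 0.205) were lost, and without Secisbp2 knockout replicate 1 that for Selenow (adjusted p = 0.137). Selenow also lost its call without Secisbp2 wild type replicate 1 (adjusted p = 0.0801) or 2 (adjusted p = 0.106), and Selenot without Secisbp2 wild type replicate 1 (adjusted p = 0.0792) or 2 (adjusted p = 0.137) or Trsp wild type replicate 1 (adjusted p = 0.0514). Gpx3 passed without Secisbp2 wild type replicate 2 (1.72, adjusted p = 0.0329), and Selenok without Trsp wild type replicate 2 (adjusted p = 0.00512) or 3 (adjusted p = 0.0390). Gpx2 passed without Secisbp2 wild type replicate 2 (-1.44, adjusted p = 0.00552) and Selenoi without Trsp wild type replicate 2 (0.55, adjusted p = 0.0339). Scaled to the selenoproteins' median ratio, the changes shifted up by 0.68 and the split became 8 higher and 5 lower, as it did at the same median level (shift 0.60).

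In Trsp knockout livers 11 of 20 genes had fewer footprints 5' of the UGA, 1 had more (Gpx2) and 8 did not pass. Gpx1 fell by 3.78 (SE 0.577, limma adjusted p = 0.000945), or by 3.14 without Trsp wild type replicate 2 (SE 0.272, adjusted p = 0.000189), Selenok by 3.08 (SE 0.475, adjusted p = 0.000945) and Txnrd1 by 1.89 on the log2 scale (SE 0.201, adjusted p = 0.00019). Txnrd2, the mitochondrial thioredoxin reductase, changed by -1.64 (SE 0.196, adjusted p = 0.000285). Other falls were those of Selenow (-1.78, on 1 and 2 reads in the knockouts), Dio1 (to 49.9% of wild type), Selenop (-0.95), Selenot (-0.93), Txnrd3 (-0.86), Selenof (-0.78) and Selenoo (-0.73). The Selenoo call was lost with the wild type groups pooled or exchanged as control, and the Selenof call with the other colony's wild type. Gpx4 (0.43), Gpx3 (0.99), Sephs2 (-0.80), Msrb1 (-0.51), Selenos (-0.19) and Selenoh (0.03) did not pass. All 3 thioredoxin reductases and 5 of the 6 genes with a UGA close to the stop codon fell, with 3 and 5 calls adjusted over the list alone (camera adjusted p = 0.210 for both). The glutathione peroxidases ranked above the other selenoproteins (camera adjusted p = 0.0211, but adjusted p = 0.125 with an estimated correlation). Of these 4, 1 rose (Gpx2) and 1 fell (Gpx1), and how far the ranking rested on Gpx2 was not tested. Without Trsp knockout replicate 2 the 12 calls came down to 7, and the call was lost for Dio1 (adjusted p = 0.0858), Selenop (adjusted p = 0.0546), Txnrd3 (adjusted p = 0.0546), Selenof (adjusted p = 0.0718) and Selenoo (adjusted p = 0.113). Without Trsp knockout replicate 1 Selenop (adjusted p = 0.0768), Selenof (adjusted p = 0.0994), Selenoo (adjusted p = 0.0994) and Selenot (adjusted p = 0.195) lost theirs, Selenot also without Trsp wild type replicate 1 (adjusted p = 0.0904) or 3 (adjusted p = 0.0815), and Selenoo without Trsp wild type replicate 3 (adjusted p = 0.0540). Sephs2 passed without either Secisbp2 knockout replicate (adjusted p = 0.0335) or Trsp knockout replicate 1 (adjusted p = 0.0451), and Gpx3 without either Secisbp2 wild type replicate (adjusted p = 0.0498). With precision weights from the read numbers the Selenow call was lost (adjusted p = 0.0538), and with the groups of the comparison alone those of Selenoo and Selenot (adjusted p = 0.0523 each). With the replicate number as a block so were those of Selenoo (adjusted p = 0.0645), Selenop (adjusted p = 0.0509), Selenot (adjusted p = 0.0720) and Txnrd3 (adjusted p = 0.0551). Under that block, which takes Trsp wild type replicate 3 out of the estimate, Selenoh turned to -1.41 and passed as lower (adjusted p = 0.0170). Scaled to the selenoproteins' median ratio, the changes shifted up by 0.69 and the split became 3 higher and 4 lower, with 2 of 3 thioredoxin reductases still lower. At the same median level the shift was 1.17 and the split 6 higher and 3 lower.

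Across the 20 genes, the footprint changes 5' of the UGA went with the mRNA changes in both knockouts. Pearson's r was 0.87 and Spearman's rho 0.80 in the Secisbp2 knockout (permutation p = 1e-05, the smallest possible, and 4e-05), and r was 0.96 and rho 0.90 in the Trsp knockout (permutation p = 1e-05 for both, the smallest possible). Without the 2 genes farthest from the median mRNA change, r was 0.79 (without Gpx1 and Dio1) and 0.78 (without Gpx2 and Gpx1). These were 2 of 7 relations computed across genes, which are not independent replicates, and the Benjamini-Hochberg adjusted p-values were 3.5e-05 for both r and 0.00014 and 7e-05 for rho.

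**Figure D2:**
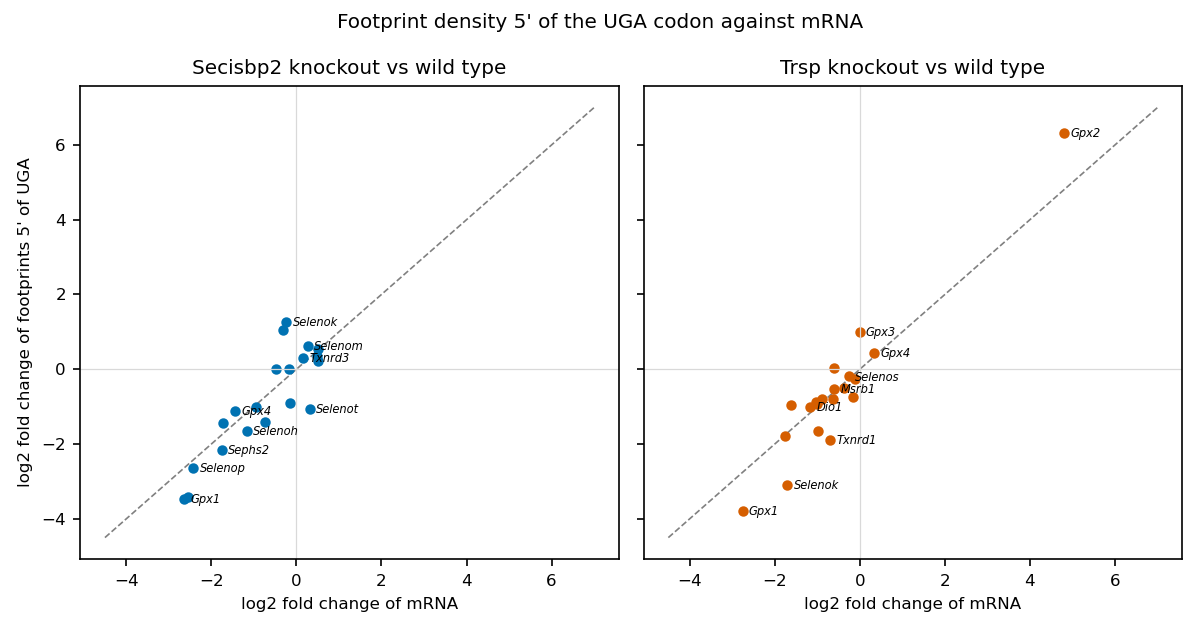
Log2 fold change of footprint density 5' of the UGA codon against that of mRNA, a point per selenoprotein, in the Secisbp2 knockout (left, 2 against 2 livers) and the Trsp knockout (right, 2 against 3 livers); the dashed line marks equal changes and crowded points carry no name. Pearson's r across the 20 genes was 0.87 on the left and 0.96 on the right, with Txnrd1 and Txnrd2 below the line in the Trsp knockout.

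Translational efficiency, the change of footprints 5' of the UGA beyond that of the mRNA, passed the threshold for 2 genes in the Trsp and 1 in the Secisbp2 knockout. In Trsp knockout livers it fell for Txnrd1, by 1.18 on the log2 scale (SE 0.217, limma adjusted p = 0.00249), and for Txnrd2, by 0.66 (SE 0.193, adjusted p = 0.0479). Footprint density over mRNA for Txnrd1 was 0.821 ± 0.0436 (SD, n = 2) against 1.91 ± 0.365 (SD, n = 3). Libraries were paired here by replicate number, a pairing that the labels do not give. Txnrd3 did not pass (0.16), and Selenok had -1.38 (adjusted p = 0.108). The genes with a UGA close to the stop codon ranked below the other selenoproteins, with 2 of 6 lower and 3 adjusted over the list alone (camera adjusted p = 0.0384, but adjusted p = 0.106 with an estimated correlation). In Secisbp2 knockout livers it fell for Selenot alone among the 20 genes tested, by 1.38 (SE 0.362, adjusted p = 0.0464). That call was lost with the wild type groups pooled, and with the other colony's wild type the change came to 0.25 (adjusted p = 0.984). With an unadjusted limma p under 0.05 there were 6 genes in the Trsp and 5 in the Secisbp2 knockout. In simulated data 58.8% and 60% of 2-fold changes of efficiency were found, so that few calls do not show few changes. The Txnrd1 call held without any single library, whereas those for Selenot and Txnrd2 were each lost in most such fits, at an adjusted p = 0.0659 for Selenot without the footprints of Secisbp2 wild type replicate 1 and 0.150 for Txnrd2 without those of Trsp knockout replicate 2. Selenok passed in the Trsp knockout without the footprints of Trsp wild type replicate 2 (-0.86, adjusted p = 0.0488) or 3 (-1.71, adjusted p = 0.0296), and Gpx2 without either Secisbp2 wild type replicate's footprints (1.52, adjusted p = 0.0334) or RNA (adjusted p = 0.0362). In the Secisbp2 knockout Selenok as higher (adjusted p = 0.00365) and Selenof as lower (-0.69, adjusted p = 0.0163) passed without the footprints of Trsp wild type replicate 2, and Gpx3 without those of Secisbp2 wild type replicate 2 (2.03, adjusted p = 0.0310). Under scaling to the selenoproteins' median ratio, 1 of the 3 thioredoxin reductases was still lower in the Trsp knockout and no call was left in the Secisbp2 knockout. At the same median level there were 0 higher and 1 lower in the Trsp knockout and 2 higher and 0 lower in the Secisbp2 knockout.

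Footprints 3' of the UGA come largely from ribosomes that have read through it. In Secisbp2 knockout livers 9 of 12 genes fell, none rose (10 had an unadjusted limma p under 0.05) and 3 did not pass, with a median log2 change of -2.29. The falls were those of Sephs2 (-3.45), Selenof (-3.31), Gpx1 (-2.94), Gpx4 (-2.94), Selenop (-2.74), Dio1 (-2.51), Selenow (-2.08), Msrb1 (-1.98) and Selenoh (-1.81), the SE lying at 0.308 for Selenop and 0.630 for Msrb1. Selenot (-0.78, adjusted p = 0.0527), Selenoi (-0.67) and Gpx3 (0.38) did not pass. Msrb1 lost its call without Secisbp2 wild type replicate 1 (adjusted p = 0.0965) or Secisbp2 knockout replicate 2 (adjusted p = 0.158), and Selenot gained one without Secisbp2 knockout replicate 1 (adjusted p = 0.0210).

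In Trsp knockout livers the density 3' of the UGA fell for 10 of 12 genes, none rose (11 had an unadjusted limma p under 0.05) and the median log2 change was -3.18. Sephs2 came down to 2.05% of wild type (log2 change -5.61, SE 0.341, limma adjusted p = 1.07e-07) and Gpx1 to 2.31% (-5.43, SE 0.362, adjusted p = 1.36e-07). The other falls were Msrb1 (-3.95), Selenot (-3.62), Selenow (-3.42), Selenop (-3.37), Dio1 (-2.99), Gpx4 (-2.76), Selenof (-2.30) and Selenoh (-1.56). Selenoi (1.63, adjusted p = 0.0532) and Gpx3 (-0.34) did not pass, but Selenoi passed as higher without Trsp wild type replicate 1 (2.39, adjusted p = 9.76e-05) or 3 (1.80, adjusted p = 0.0434). Selenoi had 13, 1 and 4 reads there in wild type replicates 1, 2 and 3, and 12 and 15 in the knockouts. It passed with no filter on low values (adjusted p = 0.0492) but not with precision weights from the read numbers (0.83, adjusted p = 0.129). All 4 genes that follow the selenium supply fell in both knockouts, 4 adjusted over the list alone in each (camera adjusted p = 0.837 and 0.753). Each of the 10 calls in the Trsp knockout held without any single library. Scaled to the selenoproteins' median ratio, the changes shifted up by 2.16 and 2.87, the split became 2 higher and 3 lower in the Secisbp2 knockout and 3 higher and 3 lower in the Trsp knockout. At the same median level the shifts were 3.05 and 3.45 and the splits 2 and 0, and 4 and 2. Under ratio scaling, the median of the 4 genes that follow the selenium supply turned to 0.08 in the Secisbp2 knockout and was -0.82 in the Trsp knockout. Selenok, Selenoo, Selenos and the 3 thioredoxin reductases were listed at 0 reads 3' of the UGA in all libraries and could not be tested.

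UGA redefinition was taken as the footprint density 3' of the UGA over that 5' of it in the same library, in percent. It is a ratio of densities in short windows and can exceed 100. The comparison addresses how far reading through UGA depends on Secisbp2. The ratio does not show which amino acid was inserted. Liver cells that kept the targeted gene may add to what is left in a knockout, which was not tested. In Secisbp2 knockout livers the values differed widely between genes. For Selenop redefinition was 36.4 ± 3.82% against 39.5 ± 3.32% in wild type (SD, n = 2 each), a log2 change of -0.11 with a 95% interval of -0.72 to 0.49 that excludes a 2-fold fall against that wild type. Trsp wild type livers were higher, at 60.3%, 60.5% and 57.1%, so that the exclusion covers its own control alone. Gpx4 was at 4.25 ± 0.173% against 15.9 ± 3.47% (log2 change -1.82, SE 0.378, limma adjusted p = 0.0241), Selenof at 43.7 ± 2.53% against 170 ± 63.5% (-1.89, SE 0.558, adjusted p = 0.0476) and Sephs2 at 16.3 ± 1.09% against 44.2 ± 17.3% (-1.29, SE 0.369, adjusted p = 0.0476).

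These 3 were the calls among 12 genes in the Secisbp2 knockout, all lower, and 5 had an unadjusted limma p under 0.05. Dio1 (0.91, adjusted p = 0.0597), Gpx1 (0.52), Selenot (0.28), Selenoh (-0.17), Selenow (-0.64), Gpx3 (-0.66), Selenoi (-1.23) and Msrb1 (at 25.0% of wild type, adjusted p = 0.119) did not pass. The set as a whole was not shown to move one way (fry adjusted p = 0.0922). With the replicate number as a block the Sephs2 call was lost (-1.29, adjusted p = 0.0888) and Msrb1 passed (adjusted p = 0.0227). With the wild type groups pooled or exchanged as control the Selenof call was lost, while Gpx4 and Sephs2 kept theirs. Against the other colony's wild type Selenot turned to -2.33 and passed as lower (adjusted p = 0.00571). The calls hung on single libraries, by their values or, for Trsp libraries, by the shared spread alone, since these do not enter the estimates. None was left without Secisbp2 wild type replicate 1, either Secisbp2 knockout replicate or Trsp wild type replicate 1; for Gpx4 the adjusted p was then 0.122, 0.137, 0.135 and 0.060. Without any of the other libraries at least 1 of the calls for Selenof and Sephs2 was lost, as without Trsp knockout replicate 1 (adjusted p = 0.0516 for both). In simulated data of the same size, 28.7% of 2-fold and 59% of 4-fold changes of redefinition were found in this comparison, so that changes of that size could be missed. Of the calls made there, 6.81% fell on unchanged genes.

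In Trsp knockout livers redefinition fell for 9 of 12 genes and rose for none (9 had an unadjusted limma p under 0.05). Sephs2 came down from 57.4 ± 3.36% (SD, n = 3) to 1.82 ± 0.576% (SD, n = 2), a log2 change of -4.81 (SE 0.337, limma adjusted p = 2.7e-05). Selenop came down from 59.3 ± 1.93% to 11.1 ± 1.36% (-2.42, SE 0.232, adjusted p = 0.000109). Gpx4 went from 23.7 ± 6.23% to 2.51 ± 0.838% (-3.19, SE 0.345, adjusted p = 0.000158) and Dio1 from 22.4 ± 3.61% to 4.68 ± 0.510% (-1.99, SE 0.274, adjusted p = 0.000548). Msrb1 (-3.44), Selenot (-2.69), Selenow (-1.64), Selenof (-1.52) and Gpx3 (-1.33) fell too. With a pseudocount of 0.1 the Gpx3 call was lost. The fall of Selenot hung on its control, as it was lost with the wild type groups pooled (-1.65, adjusted p = 0.131) and absent against Secisbp2 wild type livers (-0.0820, adjusted p = 0.874), which were at 5.67 ± 1.52% (SD, n = 2). The Selenow call was lost against Secisbp2 wild type livers too. The set moved down on balance (fry adjusted p = 0.000229).

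Trsp wild type replicate 2 stood apart from replicates 1 and 3 in both footprint windows, with a chi-square per degree of freedom of 54.5 and 58.2 against them 5' of the UGA, where replicates 1 and 3 differed by 2.92. In the 3' window these values were 34.0, 32.9 and 1.77. The Secisbp2 wild type libraries differed by more than that in the 3' window (48.5) and by 13.1 in the 5' window. Trsp wild type replicate 2 decided the result for Gpx1, whose redefinition was 17.3% in that library and 104% and 135% in the other Trsp wild type livers. Gpx1 did not pass with it (log2 change -1.66, adjusted p = 0.103) and fell without it (-2.58, SE 0.392, adjusted p = 0.000904). Selenoi, at 222%, 14.6% and 97.5% in the wild type livers and a mean of 304% in the knockouts, did not pass with it (2.13, adjusted p = 0.0851) or without it (1.04, adjusted p = 0.0509), but passed as higher without replicate 1 (2.97, adjusted p = 0.0184). That left wild type libraries with 1 and 4 Selenoi reads 3' of the UGA. With precision weights from the read numbers the Selenoi change was 1.28 (limma adjusted p = 0.103). Against Secisbp2 wild type livers, at 496 ± 18.5% (SD, n = 2), its change was -0.70 (adjusted p = 0.648). Selenoh (-1.58) did not pass. Without Trsp wild type replicate 2 there were still 9 genes that fell, Gpx1 among them, while Selenow lost its call (adjusted p = 0.0597). Without Trsp knockout replicate 2 there were 6 calls, and those for Selenof (adjusted p = 0.185), Selenow (adjusted p = 0.214) and Gpx3 (adjusted p = 0.0911) were lost. Gpx3 also lost its call without Trsp knockout replicate 1 (adjusted p = 0.0793), Selenof without Trsp wild type replicate 1 (adjusted p = 0.0742) or 3 (adjusted p = 0.0734), and Selenow without either Secisbp2 wild type replicate (adjusted p = 0.0575) or Trsp wild type replicate 1 (adjusted p = 0.0742). The values for Selenow, Selenoh and Gpx3 rest on few reads, at most 9, 17 and 6 in a library 5' of the UGA.

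Scaling each footprint window to the selenoproteins' median ratio takes a shared fall of redefinition out by construction. It shifted the redefinition changes up by 1.48 and 2.17, to 3 higher and 0 lower in the Secisbp2 knockout and 1 higher and 1 lower in the Trsp knockout. At the same median level the shifts were 2.45 and 2.28 and the splits 5 and 0, and 1 and 1.

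**Figure D3:**
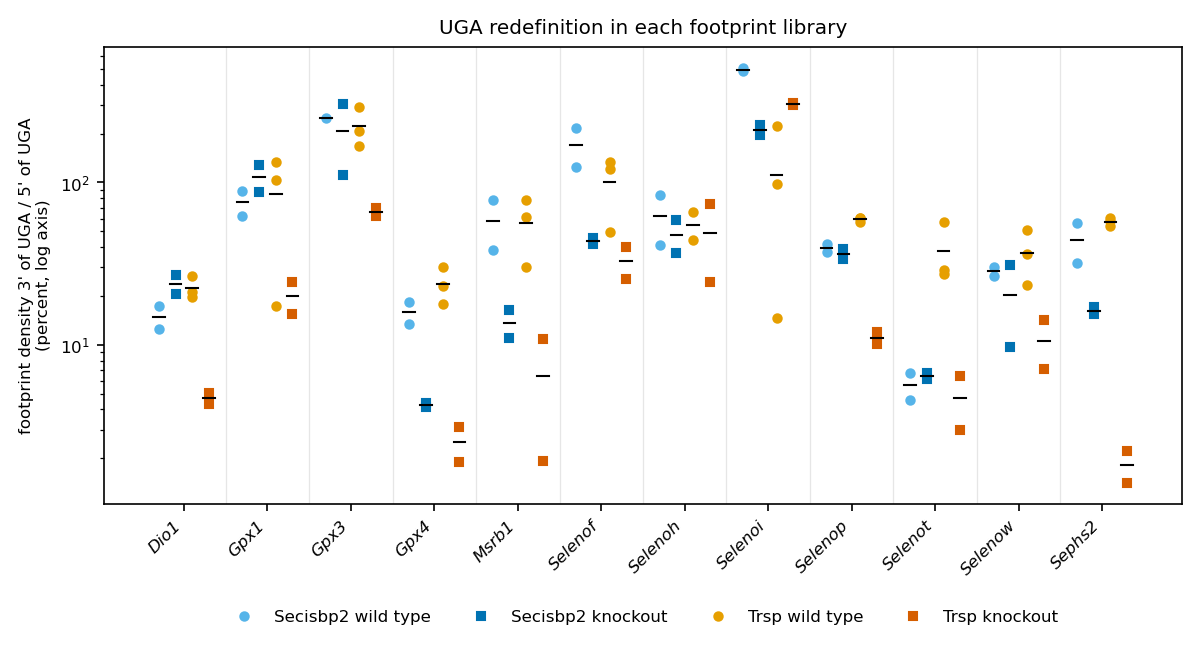
UGA redefinition, as footprint density 3' of the UGA over that 5' of it in percent on a log axis, for 12 selenoproteins; each point is a footprint library, each bar the mean of its group (2 Secisbp2 wild type, 2 Secisbp2 knockout, 3 Trsp wild type and 2 Trsp knockout livers), and a library with no reads 5' of the UGA has no point. Selenop had a mean of 36.4% in the Secisbp2 knockout and came down to 11.1% in the Trsp knockout.

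The density 3' of the UGA is the product of the density 5' of it and redefinition, and the genes reached their loss by different shares of these. In the Secisbp2 knockout, Selenop lost 2.74 log2 units 3' of the UGA, as -2.63 came from the density 5' of it and -0.11 from redefinition. For Gpx1 the parts were -3.46 and 0.52. For Gpx4 they were -1.12 and -1.82, and for Msrb1, whose whole change was -1.98, 0.02 and a redefinition at 25.0% of wild type, which did not pass. In the Trsp knockout the parts were -0.95 and -2.42 for Selenop and 0.43 and -3.19 for Gpx4.

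Whether the knockouts differed was tested by the difference of their effects, Secisbp2 minus Trsp, each against its own wild type. The Secisbp2 groups lie in separate library sets and the Trsp groups in the same set, so a library set effect can enter these differences. Redefinition was less affected by Secisbp2 loss than by Trsp loss for Sephs2 (difference 3.51, 95% interval 2.33 to 4.70, limma adjusted p = 0.0012), Selenop (2.30, SE 0.344, adjusted p = 0.0012), Dio1 (2.89, SE 0.406, adjusted p = 0.0012) and Selenot (2.97, SE 0.672, adjusted p = 0.00958). These were the 4 calls among 12 genes, none lower, 5 had an unadjusted limma p under 0.05, and each of the 4 held without any single library. Gpx4 (1.37, adjusted p = 0.0777), Gpx1 (2.18), Msrb1 (1.44), Selenow (1.00), Selenoh (1.41), Gpx3 (0.67), Selenof (-0.37) and Selenoi (-3.35, adjusted p = 0.116) did not pass. Selenoi went the opposite way to the calls and passed without Trsp wild type replicate 1 (-4.19, adjusted p = 0.0258) or 2 (-2.26, adjusted p = 0.0129). With the wild type groups pooled the Selenot call was lost (0.36, adjusted p = 0.818). Gpx1 gained a call without Trsp wild type replicate 2 (3.10, adjusted p = 0.00243) and Gpx4 without Trsp knockout replicate 1 (1.71, adjusted p = 0.0488). Selenot had 5.67 ± 1.52% in Secisbp2 wild type (SD, n = 2) and 37.8 ± 16.8% in Trsp wild type livers (SD, n = 3), so that its difference came with a difference of the wild types. Scaled to the selenoproteins' median ratio, the differences shifted down by 0.70, to 4 higher and 1 lower, and at the same median level they shifted up by 0.14, to 4 and 0.

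At the mRNA level the effects differed for 14 of 20 genes. The 3 thioredoxin reductases were all higher after Secisbp2 loss than after Trsp loss, Txnrd1 by 1.20 (SE 0.182, limma adjusted p = 0.000475), Txnrd3 by 1.18 and Txnrd2 by 0.80, and 3 passed adjusted over the list alone (camera adjusted p = 0.0988). Selenok (1.47), Selenot (1.33), Selenoi (0.89) and Selenoo (0.67) went the same way. Gpx2 (-4.95), Gpx4 (-1.78), Dio1 (-1.37), Sephs2 (-0.85), Selenop (-0.82), Selenos (-0.68) and Selenoh (-0.56) were lower after Secisbp2 loss. With the wild type groups pooled the calls for Gpx4 (-0.80, adjusted p = 0.138), Selenoi (0.37, adjusted p = 0.242), Selenot (0.62, adjusted p = 0.116) and Selenoh were lost. Gpx1 (0.12), Selenow (0.02), Msrb1 (0.12), Selenof (-0.11) and Gpx3 (-0.30) did not pass; for Gpx1 the 95% interval of the difference was -0.30 to 0.53. Of the 14, 11 held without any single library, and Gpx3 passed without Secisbp2 wild type replicate 1 (-0.56, adjusted p = 0.0321) and Selenom without replicate 2 (0.83, adjusted p = 0.0342). The calls for Selenoh, Selenos and Sephs2 were each lost without at least 6 of them, at an adjusted p = 0.0859, 0.0756 and 0.105 without Trsp knockout replicate 1. Of the 6 genes with a UGA close to the stop codon 5 were higher and 1 (Selenos) lower, with 6 calls adjusted over the list alone (camera adjusted p = 0.0988). These directions hung on the scaling: with every library at the same median level of the selenoproteins the differences shifted down by 0.90, to 1 higher and 12 lower, with 1 of the 3 reductases and 1 of the 6 genes with a UGA close to the stop codon still higher. Scaling to the median ratio shifted them by -0.06 alone and left 7 and 7.

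Footprints 5' of the UGA differed between the effects for 11 of 20 genes, 6 higher and 5 lower after Secisbp2 loss. The higher ones were Selenok (4.35), Txnrd1 (2.10), Txnrd2 (1.64), Txnrd3 (1.16), Selenoo (1.10) and Selenoi (1.05), and the lower ones Gpx2 (-7.22), Dio1 (-2.41), Selenop (-1.68), Gpx4 (-1.55) and Sephs2 (-1.36). The size for Gpx2 was set by the 0.5 RPKM added to its 0 reads in Trsp wild type, from -9.57 with 0.1 to -6.18 with 1 added, and the call was lost with the wild type groups pooled (-2.83, adjusted p = 0.225). Pooling also lost the calls for Gpx4 (-0.88, adjusted p = 0.0872), Selenoi (0.47, adjusted p = 0.276) and Selenoo. Gpx1 (0.31), Selenow (0.34), Selenof (-0.64), Selenos (-0.82), Selenot (-0.13), Msrb1 (0.53), Gpx3 (0.05) and Selenoh (-1.66) did not pass. The 3 thioredoxin reductases ranked above the other selenoproteins, with 3 calls adjusted over the list alone (camera adjusted p = 0.0431, but adjusted p = 0.355 with an estimated correlation). So did the 6 genes with a UGA close to the stop codon, of which 5 were higher and 6 passed adjusted over the list alone (camera adjusted p = 0.0419, but adjusted p = 0.336 with an estimated correlation). With every library at the same median level the differences shifted down by 0.56, to 3 higher and 7 lower, with 2 of the 3 reductases and 3 of these 6 genes still higher and 1 of the 6 lower. The median ratio shifted them by -0.02 alone, to 6 and 6. The calls for Selenoi, Selenoo and Sephs2 were each lost without any of 5 libraries, at an adjusted p = 0.0686, 0.0867 and 0.141 without Trsp knockout replicate 1. Selenof passed without Trsp wild type replicate 2 (adjusted p = 0.0168) and Selenos without Secisbp2 wild type replicate 1 (adjusted p = 0.0136). With the replicate number as a block Selenoi, Selenoo and Txnrd3 lost their calls (adjusted p = 0.0713 each).

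At the mRNA level 8 genes were shared by the 10 and 14 that fell, where independent lists would share 7. The 8 were Gpx1, Selenop, Dio1, Selenow, Sephs2, Selenoh, Selenof and Msrb1. Across the 20 genes the mRNA changes of the knockouts had a Pearson's r of 0.36 (permutation p = 0.113, adjusted p = 0.264) and a Spearman's rho of 0.40 (permutation p = 0.0788, adjusted p = 0.184), and r was 0.22 without Gpx1 and Dio1. For redefinition, r across 12 genes was 0.11 (permutation p = 0.760, adjusted p = 0.887) and rho 0.11 (permutation p = 0.730, adjusted p = 0.730), with r at 0.00209 without Dio1 and Msrb1. The 2 comparisons share no control livers, though all groups shared the estimate of the spread.

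As a background, the wild type groups, littermates of different knockouts (called colonies here) and in different library sets, were compared with each other. Beyond wild type, the labels do not state whether their genotypes are the same. At the mRNA level 9 of 20 genes differed. Gpx2 (2.27), Gpx4 (0.98), Txnrd2 (0.82) and Txnrd3 (0.79) were higher in Secisbp2 wild type livers, and Sephs2 (-1.24), Dio1 (-0.97), Selenof (-0.85), Selenot (-0.70) and Selenoi (-0.52) were lower. For Gpx4 the wild types were at 539 ± 53.8 RPKM (SD, n = 2) and 275 ± 48.8 RPKM (SD, n = 3), so the difference between the knockout effects on Gpx4 came with a difference of the wild types. Gpx1 (-0.04), Selenop (-0.26), Selenow (-0.03), Txnrd1 (-0.01), Selenok (-0.25), Selenos (-0.34), Selenoh (0.29), Msrb1 (-0.20) and Gpx3 (0.02) did not pass. Each of the 9 calls held without any single library. Selenok (-0.46, adjusted p = 0.0189), Selenos (-0.62, adjusted p = 0.00256) and Selenom (-0.80, adjusted p = 0.0151) passed without Secisbp2 wild type replicate 2 and Selenoh without Trsp wild type replicate 3 (0.42, adjusted p = 0.00768). With precision weights from the read numbers the Gpx2 call was lost (adjusted p = 0.157). Scaled to the selenoproteins' median ratio, which shifted the differences up by 0.12, there were 5 higher and 4 lower.

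Footprints 5' of the UGA differed between the wild types for 3 genes, all higher in Secisbp2 wild type (Gpx2 at 4.39, Txnrd2 at 0.80 and Txnrd3 at 0.76), and 9 had an unadjusted limma p under 0.05. Without Secisbp2 wild type replicate 1 only the Gpx2 call was left, with Txnrd2 and Txnrd3 at an adjusted p = 0.161, and the same held without Trsp wild type replicate 1 (adjusted p = 0.0951 for both) or either Trsp knockout replicate (adjusted p = 0.0670 for both). Without Trsp wild type replicate 3 these 2 calls were lost as well (adjusted p = 0.0647 for both), as they were with the replicate number as a block (adjusted p = 0.103 and 0.106). Calls in the other direction came up for Selenok without Trsp wild type replicate 2 (-1.02, adjusted p = 0.0291) or 3 (-1.87, adjusted p = 0.0242) and for Gpx3 without Secisbp2 wild type replicate 2 (-1.71, adjusted p = 0.0463). Gpx4 passed as higher without either Secisbp2 knockout replicate (0.67, adjusted p = 0.0321). Scaled to the selenoproteins' median ratio the split was 3 and 3 for these footprints, and 1 and 1 for redefinition, whose differences shifted up by 0.34. Redefinition differed for Selenot alone among the 12 genes tested (-2.61, SE 0.453, limma adjusted p = 0.00877), with 3 at an unadjusted limma p under 0.05, and not without Secisbp2 wild type replicate 2 (adjusted p = 0.102). Selenoi passed as higher without Trsp wild type replicate 1 (3.67, adjusted p = 0.0240) or 2 (1.74, adjusted p = 0.0253). With the other colony's wild type livers as control, the mRNA changes of 4 of the genes named above turned in the Trsp comparison (Selenof 0.23, Selenoi 0.14, Sephs2 0.34 and Gpx4 -0.64), as did Gpx2 (2.11, adjusted p = 0.000305), Selenot (-0.39), Selenoi (-0.01) and Txnrd2 (0.64) in the Secisbp2 comparison. Gpx2 footprints 5' of the UGA turned there too (3.49, adjusted p = 5.22e-05).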

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

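The results here came from the planned test of the difference between the knockout effects (Secisbp2 minus Trsp, limma adjusted p under the threshold), while the tests of scaling, of the shallow library, of the library set, of reads shared with Gpx1, of other liver cells and of both Selenoi explanations were chosen only after the result was seen. At the mRNA level the difference was -4.95 for Gpx2, -1.78 for Gpx4, 1.47 for Selenok, -1.37 for Dio1, 1.33 for Selenot, 1.20 for Txnrd1, 1.18 for Txnrd3 and 0.89 for Selenoi. It was -0.85 for Sephs2, -0.82 for Selenop, 0.80 for Txnrd2, -0.68 for Selenos, 0.67 for Selenoo and -0.56 for Selenoh. For footprints 5' of the UGA it was -7.22 for Gpx2, 4.35 for Selenok, -2.41 for Dio1, 2.10 for Txnrd1, -1.68 for Selenop and 1.64 for Txnrd2. It was -1.55 for Gpx4, -1.36 for Sephs2, 1.16 for Txnrd3, 1.10 for Selenoo and 1.05 for Selenoi. For redefinition it was 3.51 for Sephs2, 2.97 for Selenot, 2.89 for Dio1 and 2.30 for Selenop.

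A pattern behind several of these differences is that mRNA levels of the wild type groups themselves differed for 9 of 20 genes, with Gpx4 and Gpx2 higher and Sephs2 and Dio1 lower in Secisbp2 wild type livers. A single scaling factor between library sets was argued against, since with every library scaled to the same median level 5 genes were higher and 4 lower, so that at least 4 lay on either side. The shallow Secisbp2 wild type replicate 1 was not needed either, since all 9 calls kept their direction without it. A gene-specific effect of the library set stays open and cannot be told apart from a difference of the colonies, because 0 library sets hold both wild type groups. The biological difference of the colonies was not tested.

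Gpx2 mRNA and footprints rose in Trsp knockout livers. Reads that belong to its relative Gpx1 were argued against as the source: the share of Gpx1 reads seen in wild type allows at most 1.02 Gpx2 reads in the knockouts, against 783 seen, and Gpx1 itself came down from 144485 reads to 16740. RNA from other liver cells might bring Gpx2 and stays open, since 0 markers of such cells are among the genes of the tables. A response of hepatocytes to the loss of selenoproteins is a hypothesis that was not tested, as the lists of NRF2 targets and of selenocysteine machinery have no member in the tables. In Secisbp2 knockout livers, which lost Gpx1 as well, Gpx2 mRNA did not rise against its own wild type (-0.16, adjusted p = 0.687), while against Trsp wild type livers it was higher (2.11).

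Neither Selenoi footprints 3' of the UGA nor Selenoi redefinition fell in Trsp knockout livers. Footprints 3' of the UGA had a median log2 change of -3.18 over all 12 genes, and redefinition 1 of -1.99 over the other 11. The Selenoi result turned with the control. Against Secisbp2 wild type livers the Selenoi changes were -0.62 3' of the UGA and -0.70 for redefinition, neither past the threshold. Without Trsp wild type replicate 2 the Selenoi 3' change came from 1.63 to 0.71. Cells that kept Trsp might have gone on inserting selenocysteine, but the 95% interval of the Selenoi redefinition change starts at -0.24 and does not decide whether it rose. A 3' window too short to exclude ribosomes that wait at the UGA or at the stop codon is possible too, since the 5' window of Selenoi was 66.5 times as long as its 3' window, which was the shortest of the 12. Both stay open, as does a difference of the wild type groups, with 1 to 15 reads per Trsp library in that window and no biological explanation tested.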

How the results depend on the processing

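Precision weights, the minimum of 10 reads, the date cell left out, the block by liver and both median scalings were chosen only after the data were seen; the other settings here were planned. Leaving out libraries, 1029 values of called genes kept their call, 132 lost it and 0 reversed, while 33 values of uncalled genes gained a call. Under the other settings 1097 were kept, 102 lost and 20 reversed, with 70 gained and 9 reversed among uncalled genes. These numbers leave out uncalled genes outside the rule for named genes, namely Gpx2, Selenoi, Selenom, Selenoo and Txnrd3. A further 150 of 4688 values changed sign past the threshold in neither fit. Where a call was lost or a count moved, the cause was not tested, except where said.

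With any single library left out, the number of calls in the Secisbp2 comparison ranged from 11 to 17 for mRNA (14 with all), 7 to 11 for footprints 5' of the UGA (9), 8 to 10 for those 3' of it (9), 0 to 2 for redefinition (3) and 0 to 3 for translational efficiency (1). In the Trsp comparison the ranges were 14 to 16 (15), 7 to 13 (12), 10 to 11 (10), 6 to 9 (9) and 1 to 3 (2). For the difference of effects they were 11 to 15 for mRNA (14), 8 to 12 for footprints 5' of the UGA (11) and 4 to 6 for redefinition (4), and between the wild types 9 to 12 (9), 1 to 4 (3) and 0 to 2 (1). The redefinition calls of the Secisbp2 comparison all vanished without Secisbp2 wild type replicate 1, Secisbp2 knockout replicate 1 or 2, or Trsp wild type replicate 1.

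The 3 redefinition calls of the Secisbp2 comparison became 1 with a pseudocount of 0.1, 1 with no filter, 1 with the date cell left out, where Selenof and Sephs2 were lost, and 5 with the groups of the contrast alone. With the groups alone Selenot mRNA (0.31) and Gpx4 (-1.12), Selenos (-1.01) and Selenow (-1.44) 5' of the UGA lost their calls in the Secisbp2 comparison, as did Selenoo (-0.73) and Selenot (-0.93) 5' of the UGA and Selenof redefinition (-1.52) in the Trsp comparison. The translational efficiency call of the Secisbp2 comparison became 0 with a pseudocount of 0.1, 2 with the groups alone, 0 with the wild types pooled and 0 with the other colony's wild type. The 2 efficiency calls of the Trsp comparison became 1 with no filter, 4 with the groups alone, 1 with the wild types pooled, 4 with the other colony's wild type and 1 with precision weights. Precision weights also lost Selenow 5' of the UGA in both comparisons (-1.27 and -1.75), Gpx3 (-1.28) and Selenow (-1.70) redefinition in the Trsp comparison, the Selenoh mRNA difference of effects (-0.52) and Gpx2 mRNA between the wild types (2.14). Between the wild types, the 3 calls 5' of the UGA became 5 with these groups alone, 9 with precision weights and 6 with a minimum of 10 reads, and the redefinition call became 2 with no filter.

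Same-numbered libraries' deviations correlated at -0.42 to 0.45 within a group (5' footprints against RNA) and -0.62 to 0.67 across groups. Pairing by liver stays open. With the replicate block by number, the translational efficiency calls became 0 in the Secisbp2 and 1 in the Trsp comparison, and Selenoh 5' of the UGA in the Trsp comparison reversed to -1.41. Only Trsp wild type has a replicate 3, so for a single assay this block takes that library out of the estimates. The estimates it gave there are those of leaving that library out, while the spread differs. With a group's same-numbered libraries paired (replicate block by liver), the Trsp efficiency calls became 4. No other count moved by more than 1.5 times under a block, but calls changed behind the counts. With the block by number those lost were Selenot mRNA (0.31) and Sephs2 redefinition (-1.29) in the Secisbp2 comparison. In footprints 5' of the UGA they were Selenoo (-0.79), Selenop (-0.90), Selenot (-0.80) and Txnrd3 (-0.81) in the Trsp comparison, Selenoi (1.13), Selenoo (1.16) and Txnrd3 (1.10) in the difference of effects, and Txnrd2 (0.85) and Txnrd3 (0.82) between the wild types. It added Gpx3 (1.04), Selenoh (-1.64), Selenok (1.27) and Gpx2 (-0.90) 5' of the UGA in the Secisbp2 comparison, Msrb1 redefinition there, Gpx4 mRNA (0.48) and Selenoi 3' of the UGA (1.80) and redefinition (2.38) in the Trsp comparison, and Selenok 5' of the UGA (-1.87) and Selenoh mRNA (0.42) between the wild types. The block by liver replaced the Selenot efficiency call in the Secisbp2 comparison by Dio1 (-0.87).

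With the other colony's wild type as control, mRNA changes reversed in the Secisbp2 comparison for Gpx2 (2.11), Selenoi (-0.0124), Selenot (-0.39) and Txnrd2 (0.64), and in the Trsp comparison for Selenof (0.23), Selenoi (0.14), Sephs2 (0.34) and Gpx4 (-0.64). So did Gpx2 5' of the UGA (3.49) in the Secisbp2 comparison, and Selenot for redefinition (-2.33) and translational efficiency (0.25) in the Secisbp2 and efficiency (-1.54) in the Trsp comparison. With the wild types pooled, Selenot mRNA reversed to -0.11 in the Secisbp2 comparison. Other calls were lost without turning. Pooling lost the mRNA calls for Gpx4 (-0.85) and Selenoi (0.19) in the Secisbp2 and for Dio1 (-0.78), Selenof (-0.28), Selenoi (-0.17) and Sephs2 (-0.40) in the Trsp comparison, where Dio1 was also lost with the other colony's wild type (-0.20). Footprints 5' of the UGA lost Gpx4 (-0.72 pooled, -0.45 with the other colony) and Selenot (-0.51, -0.14) in the Secisbp2, and Selenoo (-0.59, -0.38) and, with the other colony alone, Selenof (-0.46) in the Trsp comparison. Redefinition lost Selenof (-1.40, -1.07) in the Secisbp2, and Selenot (-1.65, -0.0820) and, with the other colony alone, Selenow (-1.35) in the Trsp comparison. Efficiency calls lost by pooling were Selenot (-0.40) in the Secisbp2 and Txnrd2 (-0.66) in the Trsp comparison. Pooled controls leave the knockouts compared with each other directly, and that lost the differences for Gpx4 (-0.80), Selenoh (-0.28), Selenoi (0.37) and Selenot (0.62) in mRNA. It also lost those for Gpx2 (-2.83), Gpx4 (-0.88), Selenoi (0.47) and Selenoo (0.74) in footprints 5' of the UGA, and Selenot (0.36) in redefinition.

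Scaling to the same median log2 ratio of the selenoproteins in every library takes a shared change out by construction. Calls became 7 for footprints 5' of the UGA in the Trsp comparison, 5 and 6 for those 3' of it in the Secisbp2 and Trsp comparisons, 2 for redefinition in the Trsp comparison, 0 and 1 for efficiency, and 6 and 2 between the wild types for footprints 5' of the UGA and redefinition. In the Secisbp2 comparison, Msrb1 mRNA reversed to 0.0232. Footprints 3' of the UGA reversed for Msrb1 (0.22), Selenoh (0.10), Selenow (0.0581) and Selenot (1.27), and redefinition for Sephs2 (0.18) and Selenop (1.42). In the Trsp comparison, mRNA reversed for Selenoi (0.16), Gpx3 (0.42) and Selenoo (0.39). Footprints 3' of the UGA reversed for Gpx4 (0.16), Selenof (0.65), Selenoh (0.94) and Gpx3 (2.09), and redefinition for Dio1 (0.0444), Gpx3 (0.56), Selenof (0.74) and Selenow (0.49). With the same median level in place of the ratio, 6 genes differed between the wild types 5' of the UGA.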

Other observations

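Of the tests reported here, those of ribosome loading had their prediction written before the correlation was computed, though after the knockout effects were known, while the tests of other relations across genes, of shared genes and of sampling noise were chosen only after the result was seen. In wild type livers, Gpx1 and Selenop mRNA stood far above the other selenoproteins. Gpx1 was at 2020 ± 13.9 RPKM (SD, n = 2) in Secisbp2 and 2079 ± 105 RPKM (SD, n = 3) in Trsp wild type livers, and Selenop at 1744 ± 247 and 2092 ± 213 RPKM. Msrb1, a methionine sulfoxide reductase, Gpx4 and Sephs2 followed at 190 ± 10.5 to 539 ± 53.8 RPKM. Gpx3, the peroxidase of blood plasma, was near the lower limit at 1.58 ± 0.519 and 1.52 ± 0.155 RPKM.

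Redefinition also differed between genes in wild type livers. It was 59.3 ± 1.93% for Selenop, whose mRNA holds several UGA codons, and 57.4 ± 3.36% for Sephs2 in Trsp wild type livers (SD, n = 3). For Gpx4 it was 23.7 ± 6.23% and for Dio1 22.4 ± 3.61%. In Secisbp2 wild type livers these values were 39.5 ± 3.32%, 44.2 ± 17.3%, 15.9 ± 3.47% and 14.9 ± 3.42% (SD, n = 2). Windows of different length and position enter these ratios, so that they do not rank the genes by efficiency.

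If nonsense-mediated decay sets the mRNA loss, stronger ribosome loading in wild type liver could go with more loss. Loading was taken as footprint density 5' of the UGA over mRNA in the wild type livers of the other colony, so that no library entered both measures. The wild type mRNA level of a gene still divides both measures, which can push the relation up. Windows of different length and position enter the loading too. In the Secisbp2 knockout the relation went the opposite way: Spearman's rho across 20 genes was 0.61 (permutation p = 0.00494, adjusted p = 0.00988) and Pearson's r 0.52 (permutation p = 0.0185, adjusted p = 0.0369). The mRNAs with more footprints per mRNA lost less, and r was 0.40 without Selenoi and Selenom, the genes farthest from the median loading. Because of the shared divisor and the windows, this does not decide whether nonsense-mediated decay sets the loss. In the Trsp knockout rho was 0.0602 (permutation p = 0.802, adjusted p = 0.802) and r 0.37 (permutation p = 0.122, adjusted p = 0.122), or 0.53 without Selenot and Selenoi, which decides neither way. These were 2 relations across genes, which are not independent replicates.

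Changes of mRNA and of redefinition did not clearly go together across 12 genes. In the Secisbp2 knockout r was -0.42 and rho -0.45 (permutation p = 0.169 and 0.139, adjusted p = 0.296 and 0.244), with r at -0.71 without Selenoi and Selenot. In the Trsp knockout r was 0.03 and rho 0.13 (permutation p = 0.913 and 0.700, adjusted p = 0.913 and 0.730), with r at 0.30 without Gpx1 and Gpx4. Footprint changes 5' of the UGA had an r of 0.11 and a rho of 0.24 between the knockouts across 20 genes (permutation p = 0.666 and 0.313, adjusted p = 0.887 and 0.438), and r was -0.14 without Gpx1 and Dio1.

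Genes that fell in both knockouts numbered 6 for footprints 5' of the UGA (of 9 and 11, where independent lists would share 4.95), 9 for those 3' of it (of 9 and 10, against 7.50) and 3 for redefinition (of 3 and 9, against 2.25). The Trsp knockout footprint libraries differed 3' of the UGA by no more than sampling noise (chi-square per degree of freedom 0.659). They differed more 5' of it (4.23), and the RNA-seq libraries of that group did too (13.8), so that they were kept as separate samples.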
